A study of Homo sapiens with 4 samples.

How the data were processed

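Labelled RNA of 4 samples of the Y79 retinoblastoma line, 2 control and 2 treated with hydrogen peroxide, was hybridised to a custom one-colour human expression array. Per the labels' protocols, equal amounts of total RNA were reverse transcribed from an oligo-dT primer, amplified and labelled with Cy3, and RNA quality was monitored. Per the file headers, spot intensity was extracted with Feature Extraction 10.5.1.1, which subtracted background and detrended each array, and the header names build hg18 (NCBI build 36). The deposited intensity columns used here were the processed signal, the mean signal and the background median of each spot. The value table deposited by the authors is on the log2 scale. Set against the scanner files, it equalled the log2 processed signal minus a constant per array, to within 0.001 for 99.8% of probes on each array, with the same direction and no centring of genes. Its column medians were -3.62, -3.59, -3.61 and -3.57.

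The value of a spot was the log2 processed signal minus the 75th percentile over the non-control spots of its array. Control spots and spots with an outlier flag were left out, saturated spots were kept, and spots of 1 probe were averaged, which left 50211 of 50238 probes. A probe was kept when it was well above background on at least 2 of 4 arrays (30474 probes), and the brightest kept probe stood for a gene (20147 genes tested). Names came from the RefSeq table of assembly GRCh38, matched by unversioned accession for 28595 probes and by gene identifier for 452. The name in the file was a current symbol for 2774 probes and was kept as given for 18417, so some names are old. The builds differ, so no coordinates are given. Of 6782 genes with several kept probes, 211 had probes called in both directions.

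Groups were compared with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), using lmFit and eBayes with an intensity trend, without a block, two-sided, with Benjamini-Hochberg adjustment over all genes at 0.05. A further count, without a test, took genes whose means differed at least 2-fold with no overlap between groups. Of the 28 gene lists fixed before the data were examined, 26 had at least 5 tested members. They were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists, and with camera at an estimated correlation. Beside these, fry asked whether the members of a list moved, on balance, one way, without comparing them with other genes. Named genes followed a rule fixed before the data were examined: the 10 largest changes per direction among genes called, without overlap and with a gene symbol, up to 4 members of smallest p per list, and 12 stress genes chosen in advance. Some genes that this rule names are not reported here. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

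A gene not well above background, or saturated, on every array of a group has only a bound. Its fold is given as "at least", from the mean of the brighter group against, per array, the higher of the lowest signal among probes well above background and the probe's own value. A saturated array in the brighter group also makes the fold a lower bound, and no fold is given where an array of the dimmer group was saturated. Saturated non-control spots numbered 806 and 432 on the control arrays and 296 and 362 on the peroxide arrays.

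The fits were tested on simulated data with 20147 genes, drawn from the real means and spreads of the comparison of peroxide with control, of which 200 were changed. Of 100 genes changed by 1 on the log2 scale 49 were recovered, of 100 changed by 2 there were 88, and 17 of the 154 calls were of unchanged genes. That is a larger share than the 0.05 set by the threshold, so the real calls may also exceed it. The real comparison called 47.5% of genes, far above the share changed here, and the simulated genes varied independently, with no scaling step. The recovered shares are therefore not the power of the real comparison.

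Alternatives fixed in advance covered the background correction (normexp with offset 50), quantile and median scaling, the percentile over probes above background on all arrays, the authors' values, the filter on dim probes, a floor, the mean of a gene's probes, the variance trend, the replicate block, leaving out each array, the set tests and both thresholds. A slide or scan block was not applicable, since all arrays lay on 1 slide. Added after seeing the data were unsaturated probes alone, unsaturated probes above background on all 4 arrays, and scaling to the mean of 214 spots of 7 E1A spike-in probes.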

Results

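Gene expression was measured in Y79 cells, a human retinoblastoma line that grows in suspension, with and without exposure to hydrogen peroxide, an oxidant. One-colour arrays were hybridised with labelled RNA from 2 control samples and 2 peroxide-treated samples. The labels gave neither the concentration nor the duration of the exposure, and did not say whether the treated samples shared one exposure. Nothing stated that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical, and the small number of arrays limits the precision. The 75th percentile of the processed signal was 1148 and 622 on the control arrays and 267 and 330 on the peroxide arrays. The share of spots well above background was 62.7% and 60.7% on the control arrays and 53.9% and 55.1% on the peroxide arrays. All 4 arrays lay on 1 slide with controls and treated samples at different positions, so array position and group cannot be told apart. Profiles correlated across genes, which are not independent replicates, at Pearson r = 0.983 between controls, 0.993 between treated samples and 0.926 to 0.943 between groups.

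The comparison of treated with control cells asked how Y79 gene expression responded to peroxide stress. Immediate early, heat shock, metallothionein, cholesterol synthesis and hypoxia or glycolysis genes lay higher in treated cells, as lists tested against all other genes, relative to the 75th percentile of each array. The list of proteasome subunit genes lay lower, with 13 of 31 members lower and 2 higher. These list calls used a preset correlation, and none held with an estimated one. Of 20147 genes tested with limma, 5455 were higher and 4121 lower after peroxide at the adjusted threshold of 0.05. Changes of at least 2-fold with no overlap between groups were seen for 3400 genes in the higher direction and 2627 in the lower. Groups did not overlap for 78.3% of genes, where chance gives 33.3%. On probes above background and below saturation on all 4 arrays, 4700 genes were higher and 3331 lower. The total of 9576 changed genes fell to 3797 without peroxide replicate 1 and to 4410 without peroxide replicate 2, fits that assume the lone treated sample varies like the controls. Among the genes named below, the calls of GPX1, DDIT3, HSPA1A, SQSTM1, GPX4, MSRB1, RPL22, H3C2, H2AC18, CDC45 and LIG3 were lost without either peroxide replicate. Those of HSPA5, AURKB, CDT1 and UQCRB were lost without replicate 1, and that of SDHC without replicate 2. Scaling to the spike-in control probes, chosen after seeing the data, moved the median of all genes by -1.39 on the log2 scale and left 570 genes higher and 15204 lower, so every direction given here is relative to the bulk of the genes.

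Among the genes with the largest rise, CX3CR1, the fractalkine receptor, was at least 38.8-fold higher, the transcription factor EGR3 at least 29.7-fold, the cytokine OSM at least 32.3-fold, the kinase ULK2 at least 14.9-fold, the protease inhibitor CST6 at least 13.1-fold and CFAP43 at least 11.6-fold. All of these were not well above background on either control array, and their adjusted p from limma ranged from 0.00069 for EGR3 to 0.00090 for CFAP43. GLI1, a transcription factor of the Hedgehog pathway, rose 53.7-fold (log2 fold change 5.75 ± 0.15, SE, n = 2 per group, limma adjusted p = 0.00060). S100P rose 52.3-fold (5.71 ± 0.17) and the inducible chaperone HSPA6 47.1-fold (5.56 ± 0.60). The value for HSPA6 was 4.56 without control replicate 1 and 6.56 without control replicate 2. PGC was higher and above background on 1 of the 2 control arrays. Its log2 fold change was 4.97 with low signals raised to a floor, 4.46 without control replicate 1 and 6.79 without control replicate 2. With normexp the log2 fold changes were 5.12 for GLI1, 4.75 for S100P and 3.31 for PGC.

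The genes with the largest fall included NIBAN1, which was 27.5-fold lower (log2 fold change -4.78 ± 0.60, limma adjusted p = 0.0027), and CCDC71L, which was 16.1-fold lower (-4.01 ± 0.15). The log2 fold change of NIBAN1 was -3.85 without control replicate 1, -5.71 without control replicate 2 and -3.14 with normexp. That of CCDC71L was -2.99 with normexp and -3.26 with the mean of its probes. KLHDC7B was at least 15.3-fold lower, GPX8, an endoplasmic reticulum peroxidase, at least 12.9-fold, SFXN2 at least 11.7-fold, EME2 at least 8.86-fold, CALD1 at least 8.53-fold and CACNA2D3 at least 4.71-fold. The probe named for the pseudogene RPS26P11 was at least 6.39-fold lower, and its origin is uncertain because near-identical copies exist. These 7 genes with a bound were not well above background on either peroxide array.

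Immediate early genes, which are induced without new protein synthesis, were higher for most members. Of 26 measured members 23 were higher, none was lower and 3 did not pass (24 higher adjusted over the list alone), with a median log2 fold change of 1.81 (2.24 with members at their bounds). FOS rose 11.2-fold (3.48 ± 0.14), EGR4 19.9-fold (4.31 ± 0.25) and ARC 4.87-fold (2.28 ± 0.12). The list stood above all other genes by camera at a preset correlation (adjusted p = 6.6e-09), and the call was lost with an adjusted p = 0.50 with an estimated correlation, as was that of each list called here.

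Heat shock genes, which encode protein-folding chaperones, were higher for 19 of 23 members, none was lower and 4 did not pass (19 higher adjusted over the list alone), with a median log2 fold change of 1.47 that was 0.55 with quantile scaling. The list median lay 0.46 higher on control 2 than on control 1. The co-chaperone BAG3 rose 16.6-fold (4.05 ± 0.36), DNAJB1 7.41-fold (2.89 ± 0.16), the collagen chaperone SERPINH1 4.15-fold (2.05 ± 0.14) and HSPH1 3.94-fold (1.98 ± 0.18). HSPA1A rose 5.55-fold (2.47 ± 0.78, adjusted p = 0.043), with control values of -1.91 and 0.69. Its log2 fold change was 1.18 without control replicate 1 and 3.77 without control replicate 2. The call was lost with quantile scaling (adjusted p = 0.060) and without an intensity trend (adjusted p = 0.085). Its near-identical copy HSPA1B may share its probes. Camera gave an adjusted p = 1.4e-05, and adjusted p = 0.63 with an estimated correlation. Of the members 5 were saturated on at least 1 array, and without saturated probes 16 were higher and 1 lower.

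Metallothionein and zinc response genes, which bind or export metal ions, were higher for 8 of 9 members, with none lower (9 higher adjusted over the list alone) and a median log2 fold change of 1.69. The list median lay 0.42 higher on control 2 than on control 1. The zinc exporter SLC30A1 rose 10.4-fold (3.38 ± 0.17), MT1X 7.38-fold (2.88 ± 0.21) and MT1H 6.33-fold (2.66 ± 0.24), although probes of the similar MT1 genes may share signal. Camera gave an adjusted p = 0.00043, and adjusted p = 0.76 with an estimated correlation.

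Cholesterol synthesis genes were higher for 14 of 21 members and lower for 1, with a median log2 fold change of 1.103 that turned to -0.28 on the spike-in scale. HMGCS1, an early enzyme of the pathway, rose 4.91-fold (2.30 ± 0.14) and the isomerase IDI1 3.33-fold (1.74 ± 0.14). The counts were 14 higher and 1 lower adjusted over the list alone, and camera gave an adjusted p = 0.00015, with adjusted p = 0.67 with an estimated correlation. Among 15 fatty acid synthesis genes 6 were higher and 1 was lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.20). By fry, which asks whether members move one way, the adjusted p was 0.018. The genes included ACACB at 8.24-fold, ACSL3 at 3.31-fold and SCD at 2.68-fold higher and THRSP at 2.51-fold lower. FASN had a log2 difference of 0.10 ± 0.14 that did not pass (adjusted p = 0.59).

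Hypoxia response and glycolysis genes were higher for 19 of 25 members, with none lower (20 higher adjusted over the list alone) and a median log2 fold change of 0.98 that turned to -0.41 on the spike-in scale. P4HA1, a collagen prolyl hydroxylase subunit, rose 8.88-fold (3.15 ± 0.26), the glycolytic enzyme ALDOC 7.58-fold (2.92 ± 0.14) and the mitophagy receptor BNIP3 2.67-fold (1.42 ± 0.15). Camera gave an adjusted p = 3.4e-05, and adjusted p = 0.63 with an estimated correlation. Of the members 3 were saturated on at least 1 array, and without saturated probes 16 of 23 were higher and 1 lower.

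Targets of NRF2, the transcription factor of the antioxidant response, moved both ways: 3 of 23 were higher, 8 were lower and 12 did not pass (3 and 8 adjusted over the list alone). The aldo-keto reductase AKR1B10 fell 6.35-fold (-2.67 ± 0.17), the cystine transporter SLC7A11 5.48-fold (-2.45 ± 0.19), the quinone reductase NQO1 9.52-fold (-3.25 ± 0.66) and SQSTM1 1.95-fold (-0.97 ± 0.20), with NQO1 above background on 1 of the 2 peroxide arrays. NQO1 had a log2 fold change of -4.26 without control replicate 1 and -2.24 without control replicate 2, and its call was lost with normexp (-1.55, adjusted p = 0.051). The list median of -0.90 did not pass by camera (adjusted p = 0.12). By camera it passed with normexp (adjusted p = 0.014), quantile scaling (0.047), no filter on dim probes (0.0038), the mean of a gene's probes (0.037) and the replicate block (0.048). The list median was -0.84 without peroxide replicate 1 and -0.85 without peroxide replicate 2. It was -0.16 without control replicate 2 and -1.095 without control replicate 1. Such fits leave 1 sample in a group, so only their list medians are given here. The control arrays stood apart on these genes, since HMOX1, which encodes heme oxygenase, lay at 3.30 and 6.73 on the controls, the latter a saturated spot, and at 5.89 and 5.87 on the treated arrays. TXNRD1 lay at -1.71 and 0.38 on the controls and at -2.29 and -1.85 on the treated arrays. Neither HMOX1 (adjusted p = 0.51) nor TXNRD1 (adjusted p = 0.12) passed in limma. HMOX1 was called lower without control replicate 1 (-0.85, adjusted p = 0.0024) and higher without control replicate 2 (2.58, adjusted p = 4.2e-05). TXNRD1 passed with the replicate block (adjusted p = 0.017) and without control replicate 1 (-2.45, adjusted p = 0.00031).

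**Figure D1:**
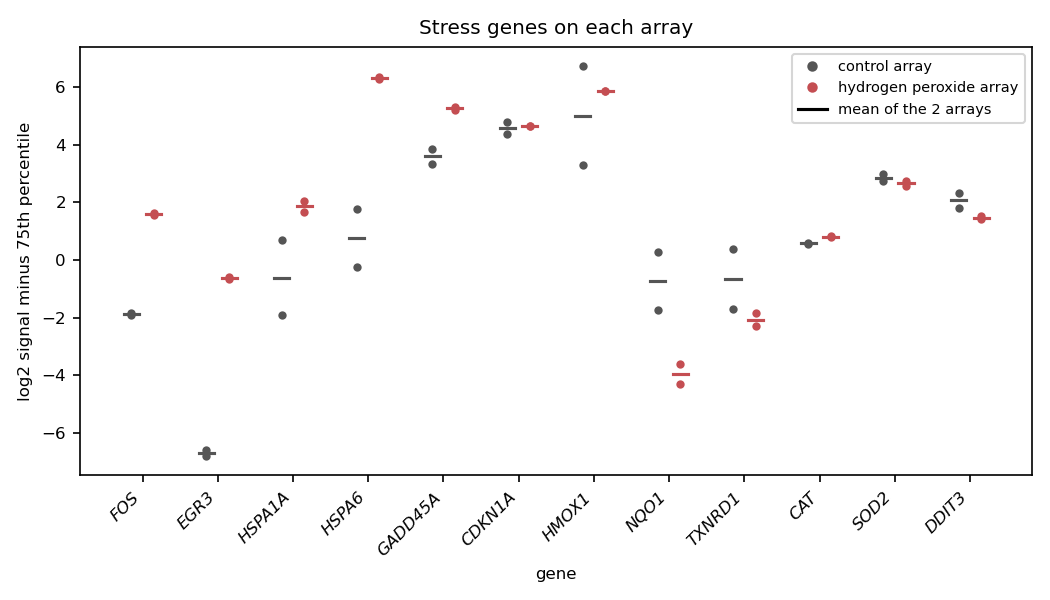
Log2 signal minus the 75th percentile of each array (vertical axis) for 12 stress genes (horizontal axis), with grey points for the 2 control arrays, red points for the 2 hydrogen peroxide arrays and bars for the group means. FOS lay higher on both peroxide arrays by 3.48, whereas the HMOX1 controls lay at 3.30 and 6.73 (saturated), on either side of the treated arrays.

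Among 24 genes of peroxide and superoxide removing enzymes 5 were higher and 5 lower (5 and 5 adjusted over the list alone; camera adjusted p = 0.48, passing lower with quantile scaling at 0.030). Apart from GPX8, GLRX fell 11.5-fold (-3.52 ± 0.32) and MSRB1 1.72-fold, whereas GPX4, which reduces lipid peroxides, rose 1.89-fold (0.92 ± 0.15). GPX1 was saturated on both control arrays and has no fold, and its call was also lost with quantile scaling (adjusted p = 0.43). CAT, which encodes catalase, differed by 0.23 ± 0.12 and SOD2 by -0.20 ± 0.14, and neither passed (adjusted p = 0.18 and 0.29). SOD2 passed without control replicate 2 (adjusted p = 0.0499).

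Cytosolic ribosomal protein genes were higher for 34 of 35 members (35 adjusted over the list alone; camera adjusted p = 6.1e-07, and adjusted p = 0.79 with an estimated correlation), but 29 of the 35 were saturated on all 4 arrays and have no fold. The median of 1.51 became 0.12 with quantile scaling, which ended the call (adjusted p = 0.18). By fry, which compares the list with no other genes, it did not pass (adjusted p = 0.13). On unsaturated probes 12 of 17 members were higher and 2 lower, with a median of 0.97 (camera adjusted p = 0.0048, adjusted p = 0.51 with an estimated correlation). After scaling, the ceiling was lower on the control arrays than on the peroxide arrays, so this filter favoured members higher after peroxide. RPL22, one of the 2 members saturated on no array, rose 2.33-fold (1.22 ± 0.20) and turned to -0.17 on the spike-in scale. Histone genes were higher for 8 of 13 members and lower for 1 (11 and 1 adjusted over the list alone), with H2AC18 at 2.00-fold and H3C2 at 1.82-fold higher, and a median of 0.86 that turned to -0.52 on the spike-in scale. The histone call (camera adjusted p = 0.023, adjusted p = 0.63 with an estimated correlation) was lost without saturated probes (adjusted p = 0.099), with normexp (0.13), with quantile scaling (0.27), without peroxide replicate 1 (0.060) and without peroxide replicate 2 (0.052). Proteasome subunit genes were lower for 13 of 31 members and higher for 2 (13 and 2 adjusted over the list alone), with PSMC5 at 2.96-fold, PSMC2 at 2.00-fold and PSMD2 at 1.91-fold lower. Their median log2 fold change was -0.30 (camera adjusted p = 0.023, adjusted p = 0.63 with an estimated correlation), and the median was -0.72 with quantile scaling. The call was lost without peroxide replicate 2 (adjusted p = 0.11).

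**Figure D2:**
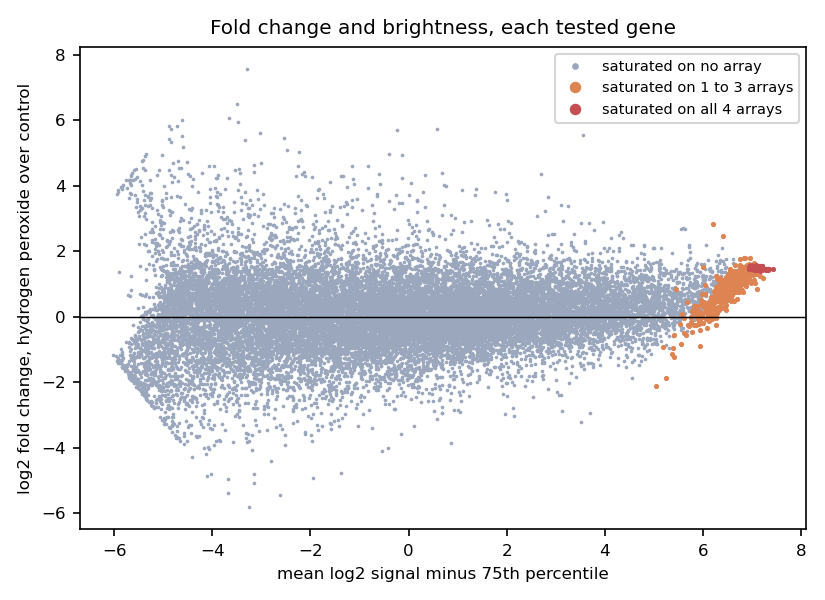
Log2 fold change of peroxide over control (vertical axis) against the mean log2 signal minus the 75th percentile (horizontal axis) for each of 20147 genes, coloured by the number of saturated arrays. The 221 genes saturated on all 4 arrays lie in a narrow band with a median of 1.51.

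Genes of the p53 pathway moved in both directions, with 11 of 25 higher and 6 lower (11 and 7 adjusted over the list alone; camera adjusted p = 0.82). The quinone oxidoreductase gene TP53I3 fell 14.3-fold (-3.84 ± 0.21), whereas the phosphatase PPM1D rose 3.20-fold (1.68 ± 0.12), GADD45A 3.16-fold (1.66 ± 0.20) and TRIAP1 2.41-fold (1.27 ± 0.12). CDKN1A, which encodes the cell cycle inhibitor p21, differed by 0.05 ± 0.18 (adjusted p = 0.82). In the BCL2 family 8 of 19 were higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.18, fry adjusted p = 0.042), with BAD at 2.63-fold higher and BMF at 3.59-fold lower, both of them promoters of cell death.

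Among 23 genes of the ATF4 and amino acid stress response 11 were higher and 5 lower (11 and 5 adjusted over the list alone; camera adjusted p = 0.82), and without saturated probes 5 were higher and 4 lower. PPP1R15A, which directs dephosphorylation of the initiation factor eIF2alpha, rose 3.20-fold, NUPR1 fell 6.71-fold, CTH fell 2.48-fold and DDIT3 fell 1.52-fold (adjusted p = 0.046), a call also lost without an intensity trend (adjusted p = 0.097). Of 20 endoplasmic reticulum chaperone genes 3 were higher and 5 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.48, passing lower with normexp at 0.019 and with quantile scaling at 0.045). SDF2L1 was at least 4.31-fold lower (1 control array saturated) and HSPA5 1.94-fold higher. The probes of HSPA5 disagreed, 1 higher and 1 lower, and the mean of its probes did not pass (0.26, adjusted p = 0.15).

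Of 31 genes of G1/S and DNA replication 4 were higher and 7 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.70, passing lower with normexp at 0.027 and with quantile scaling at 0.029), with CDC45 2.04-fold lower. The licensing factor gene CDT1 was higher but has no fold, since 1 control array was saturated, and was not called with quantile scaling (adjusted p = 0.070). Of 27 genes of G2/M and mitosis 6 were higher and 6 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.70, passing lower with normexp at 0.017), with MKI67 at 3.65-fold lower and AURKB at 1.81-fold higher. Homologous recombination repair had 2 of 18 higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.30, passing lower without the filter on dim probes at 0.024), with RAD51C at 2.04-fold lower. Base excision and single strand break repair had 5 of 21 higher and 5 lower (6 and 5 adjusted over the list alone; camera adjusted p = 0.87), with LIG3 at 2.16-fold lower, a call lost with the mean of its probes (adjusted p = 0.058).

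Oxidative phosphorylation subunits were higher for 10 of 31 and lower for 3 (10 and 3 adjusted over the list alone; camera adjusted p = 0.42), with UQCRB at 1.90-fold higher and SDHC at 1.95-fold lower, and 8 members were saturated on at least 1 array. Autophagy and lysosome genes were higher for 3 of 26 and lower for 4 (3 and 4 adjusted over the list alone; camera adjusted p = 0.72), with ATG4A at 2.12-fold lower. NF-kB and inflammatory genes were higher for 1 of 10 and lower for 3 (1 and 2 adjusted over the list alone; camera adjusted p = 0.72), with NFKB1 at 3.19-fold lower.

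Photoreceptor genes moved both ways, with 6 of 29 higher and 10 lower (6 and 10 adjusted over the list alone; camera adjusted p = 0.38). CRX, a transcription factor of photoreceptor differentiation, rose 5.18-fold (2.37 ± 0.15) and the rod transducin gene GNAT1 4.24-fold (2.09 ± 0.20), whereas the rod phosphodiesterase gene PDE6B fell 3.50-fold (-1.81 ± 0.13) and the disc protein gene ROM1 3.25-fold (-1.70 ± 0.13). Among 13 retinal progenitor genes 2 were higher and 4 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.70), with the Notch ligand DLL1 at 4.53-fold higher and ATOH7 at 6.26-fold lower.

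Leukocyte markers were higher for 3 of 8 with none lower (3 adjusted over the list alone; camera adjusted p = 0.38, fry adjusted p = 0.0051), with a median of 0.59 that turned to -0.80 on the spike-in scale, and included ITGAM at 10.04-fold higher, above background on 1 of the 2 control arrays, and CD14 at 4.37-fold higher. Of 12 leukocyte markers on the array, 7 were well above background on both control arrays and 6 on both peroxide arrays. None was detected on both peroxide arrays and no control array, whereas 2 were detected on both control arrays and no peroxide array. Glia markers were higher for 3 of 6 and lower for 2 (3 and 2 adjusted over the list alone; camera adjusted p = 0.72), including GFAP at 11.5-fold and APOE at 2.82-fold higher. The log2 fold change of GFAP, 3.52, was 2.59 without control replicate 1 and 4.46 without control replicate 2. Of the pigment epithelium markers 3 and of the fibroblast markers 2 were measured, too few for a list test.

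**Figure D3:**
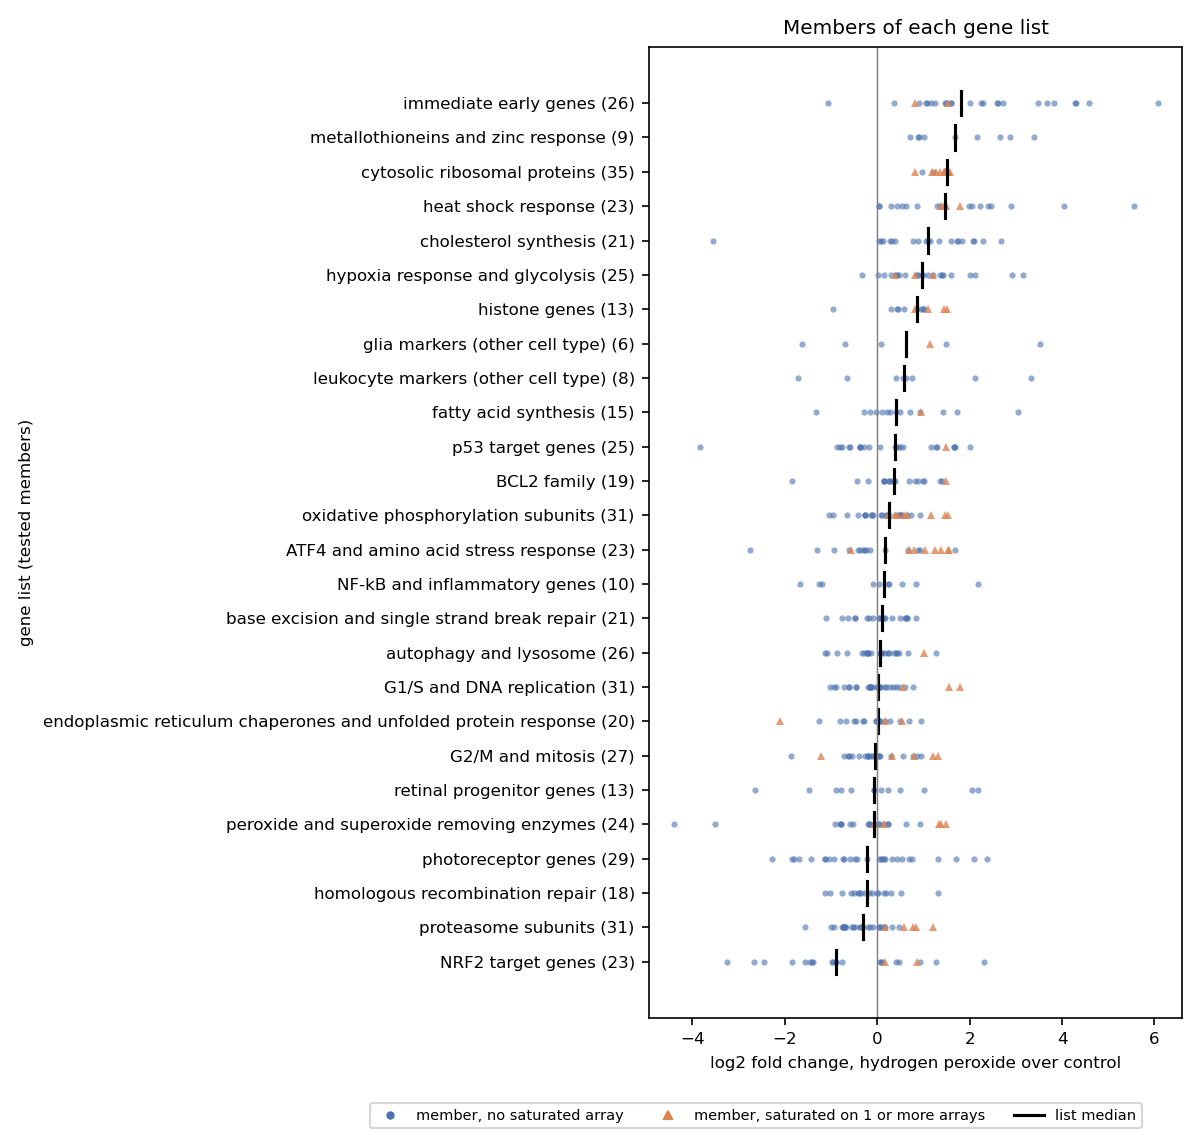
Log2 fold change of peroxide over control (horizontal axis) for the members of each of 26 gene lists (vertical axis, with the number of tested members), as blue circles for members saturated on no array and orange triangles for members saturated on 1 or more arrays, with bars for list medians. Immediate early genes had the highest median, 1.81, and NRF2 target genes the lowest, -0.90, on the 75th percentile scale.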

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

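The tests in this part were chosen after the results were seen. The E1A spike-in probes, control probes that the comparisons do not use, stood apart from the gene probes. The 75th percentile of the gene probes relative to the spike-ins was -0.54 and -0.51 on the control arrays and -1.99 and -1.84 on the peroxide arrays, a difference of -1.39 on the log2 scale. Dimmer scanning or hybridization of whole arrays would lower spike-in and gene probes alike, and the difference of -1.39 argues against it, since differences within groups were 0.03 and 0.15. RNA degradation stays open: the Spearman rho of gene length with log2 fold change across 11801 genes was -0.13, but genomic length is not transcript length and genes are not independent. Less polyadenylated RNA per amount of total RNA after peroxide, a biological difference, and unequal addition of spike-ins or RNA to the samples were not tested and stay open.

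The rise of the ribosomal protein list may come in part from saturated spots. Members saturated on all 4 arrays, 29 of 35, had a median log2 fold change of 1.53, and each lay within 0.063 of 1.51, the difference between groups of the 75th percentiles that a spot at the ceiling of the scanner takes on after scaling. Leaving out probes flagged as saturated did not end the call at the preset correlation, but cannot settle how far saturation accounts for the list. On unsaturated probes 12 of 17 measured members were called higher and 2 lower, with a median of 0.97 (camera adjusted p = 0.0048 at the preset correlation, 0.51 at an estimated one). Only 2 of the 35 members were saturated on no array with their brightest probe, so most of these 17 were read from other probes. After scaling, the ceiling lay at 5.84 and 6.72 on the control arrays and at 7.94 and 7.63 on the peroxide arrays. At this brightness, leaving out saturated probes thus drops signals that are high in controls and keeps those high only after peroxide. The rise on unsaturated probes may come in part from this selection. Whether control signals just under the ceiling were held down was not tested. For the members saturated on all 4 arrays, saturation and a real change cannot be told apart, since the ceiling fixes their values. A biological change was not tested.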

How the results depend on the processing

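The spike-in scaling and the settings without saturated probes were chosen after seeing the data; the other settings were fixed before the data were examined. Of 85 named genes called, 68 kept their direction and call in each of the 15 planned settings that gave them a value, and above background on all 4 arrays 75 of 91 named genes had one. Leaving out 1 array gave 3797 to 12276 changed genes, 2058 to 7187 higher and 1739 to 5089 lower, with 6 to 9 lists called; the low ends came without a peroxide replicate, where fewer samples remain and the lone sample is assumed to vary like the controls. Without the filter on dim probes 31371 genes were tested and 16332 changed, 12111 higher and 4221 lower, against 4121 lower with the filter. There 10403 were at least 2-fold higher, and the median of all genes moved by 0.38. The lowest scaled signal well above background was -5.71 and -5.33 on the control arrays and -4.27 and -4.32 on the peroxide arrays. Probes near background can thus read higher after peroxide without a change. Genes at least 2-fold lower numbered 985 with normexp, 1628 on probes above background on all 4 arrays and 1634 on such unsaturated probes; at 1.5-fold, 5800 were higher and 4497 lower. Normexp called 69.7% of changed genes higher, against 57.0%, and moved the median of all genes by 0.22, and 28 of 91 named genes came over 1.5 times nearer to no change, as its offset shrinks folds of dim genes; quantile scaling moved it by -0.12 and the percentile over probes above background on all arrays by -0.11. Except where stated, the cause was not tested.

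Spike-in scaling, which shifts the groups against each other, gave 15774 changed genes, 570 higher and 15204 lower, with 444 at least 2-fold higher and 12525 lower. Of 26 list medians 15 changed sign there, 11 of them called in neither setting; the others were hypoxia and glycolysis (-0.41), cholesterol synthesis (-0.28), leukocyte markers (-0.80) and histones (-0.52). Log2 fold changes reversed there, and called in at least 1 of the settings, were CAT -1.16, CDKN1A -1.33, FASN -1.29, GPX4 -0.47, RPL22 -0.17, H3C2 -0.52, H2AC18 -0.39, TRIAP1 -0.12, HSPA5 -0.43, AURKB -0.53 and UQCRB -0.46. GPX1 also changed sign, to -0.0059, but it was saturated on both control arrays, so that is no measured direction. The median of endoplasmic reticulum chaperones turned to -0.15 with normexp and -0.33 with quantile scaling, and that of G1/S and DNA replication to -0.12 and -0.38. HMOX1 was called lower, at -0.85, without control replicate 1, against the saturated spot of control 2, and higher, at 2.58, without control replicate 2. With the correlation estimated per list, 0 lists were called by camera, against 8, and 1 had an unadjusted p under 0.05; fry, which compares no list with other genes, called 10. The correlation was estimated from 2 residual degrees of freedom.

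With replicate number as a block, 5129 genes were higher and 3908 lower (9037 in all), and 9 lists were called, NRF2 targets added. Same-numbered samples did not deviate together (correlation across genes -0.08). This value, from 4 arrays, cannot settle whether same-numbered samples shared a culture or handling.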

Other observations

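Gene families grouped by the stem of their symbol, on unsaturated probes, were examined after seeing the data. Of 118 families with at least 12 members, histone genes had the smallest p: 45 of 64 names were higher and 2 lower (median log2 fold change 0.90, camera adjusted p = 7.8e-06), with H2AC21 at 1.13 ± 0.12 and H4C5 at 1.07 ± 0.13. Some old names were kept, so a gene may count under 2 names, as H2AJ (0.69) and H2AFJ (-0.40) may. RNA was reverse transcribed from an oligo-dT primer, so histone values here and in the fixed list read polyadenylated transcripts. Whether their level or their polyadenylation changed was not tested. Genes named for large ribosomal subunit proteins, pseudogenes included, were higher for 25 of 32 and lower for 4 (median 1.19, camera adjusted p = 2.6e-05), with RPL23A at 1.29 ± 0.11. Several lay just under the saturation ceiling of control 1, 5.84, such as RPL10L at 5.72 and RPL29 at 5.68 in controls. The ceiling was 7.94 and 7.63 on the peroxide arrays, so leaving out saturated probes favoured rises at this level. Others lay far below, such as RPL15 at 2.53 and RPL28 at -0.28. Keratin-associated protein genes, hair shaft proteins, were higher for 15 of 21 with none lower (median 1.01, camera adjusted p = 0.00034), with KRTAP5-8 at 3.65 ± 0.33 and KRTAP1-3 at 2.66 ± 0.15. These 2 were bright in controls (means 1.02 and 2.46), but many other members were dim, such as KRTAP5-9 at -3.47 and KRTAP5-7 at -3.84. The lowest signal well above background was -5.71 and -5.33 on the control arrays and -4.27 and -4.32 on the peroxide arrays. Dim members could thus read higher without a change. Kinesin genes, which encode microtubule motors, were lower for 14 of 34 and higher for 3 (median -0.38, camera adjusted p = 0.043), with KIF21A at -1.29 ± 0.14 and KIF3A at -1.29 ± 0.15 and, in the other direction, KIF17 at 2.28 ± 0.39. All these genes were named after their values were seen, near-identical histone, ribosomal and keratin-associated copies may share signal, and on the spike-in scale the medians were -0.44 for histones, 0.06 for ribosomal, -0.38 for keratin-associated and -1.77 for kinesin genes. With an estimated correlation the adjusted p was 0.94 for each family, so the calls rest on the preset correlation.

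The control arrays differed on some lists, without a test. The median of NRF2 targets was 0.78 higher on control 2 than on control 1, that of heat shock genes 0.46 and that of metallothioneins 0.42, against 0.04 over all genes, whereas immediate early genes differed by 0.02 and endoplasmic reticulum chaperones by -0.06. Ribosomal protein genes, mostly saturated, differed by 0.88. Between the peroxide arrays the difference was -0.10 for NRF2 targets and for heat shock genes and 0.08 for metallothioneins. HSPA6 lay at -0.23 on control 1 and 1.78 on control 2. Over all genes, 1178 lay more than 1 apart on the log2 scale between the controls and 648 between the peroxide arrays.

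Genes detected after peroxide alone may include transcripts that run on from a highly expressed neighbour, a hypothesis whose test was set before its result was seen. Of 122 protein-coding genes detected on both peroxide arrays and no control array, 63.1% had an immediate neighbour in gene order that was highly expressed in controls, against 41.1% of 4356 genes detected on no array. For the fifth neighbours the shares were 58.2% and 54.3%, so the excess was larger by 18.1 percentage points for immediate neighbours (95% bootstrap interval 6.74 to 30.2, two-sided permutation test p = 0.0025). A rival explanation, that dim genes lie beside highly expressed genes whichever way they moved, was not excluded. In a test added after that result but before its own was seen, against 539 protein-coding genes placed in gene order and detected on both control arrays and no peroxide array, the excess was 6.77 points (interval -6.48 to 19.6, permutation test p = 0.31). These control-only genes were brighter in controls (median -4.29) than the newly detected genes (-6.75) or those detected on no array (-7.63). The sets were thus not matched for level. That median of -4.29 lay near the lowest signal well above background on the peroxide arrays, -4.27 and -4.32, so such genes could be lost with little change. Run-on transcription therefore cannot be separated from this rival here, and no strand or distance was examined.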
